A study of Homo sapiens with 6 samples.

How the data were processed

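The series measured gene expression in human coronary artery smooth muscle cells, the primary contractile cells of the heart's artery wall. Retroviral shRNA was directed at the alternatively spliced L insert of CK1-alpha, so that the isoform carrying this insert, CK1-alpha-LS, was the target, and cells carrying a vector control served for comparison. There were 3 control and 3 knockdown arrays, and the labels place 1 array of each group in each of 3 numbered pairs. Whether the pairs came from separate donors or cultures is not given in the sources used here. The p-values of the paired fit rest on the spread of the 3 pair differences, which may be technical, and on the variance of other genes.

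Per the labels, total RNA was taken with a column kit, labelled with biotin by a whole-transcript terminal labelling kit and read on exon-level arrays, and the scans were summarised with Affymetrix Expression Console 1.1. RMA is named in the submitters' processing notes. The deposited values were linear intensities, 1 per probe set and array, for 287329 probe sets. Array medians lay between 82.9 and 98.7, and the smallest values were far below 1, so the values were not the log2 output that RMA usually gives. The background correction, the scaling between arrays and the genome build are not given in the sources used here. Between 18.1% and 20.1% of the probe sets of an array lay below an intensity of 16. For arrays, their number limits the precision.

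The test had been fixed for log2 values, with log2 taken first if the values proved linear. An offset of 16 was therefore added before log2, chosen after the values were seen to be linear, and offsets of 1 and 64 were tried as alternatives. All fold changes are on this log2(intensity + 16) scale, which understates the change of dim genes. No other scaling was applied in the main setting.

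Probe sets were named from a platform annotation table: 261273 carried 1 gene symbol, 9155 carried several and 16901 had no symbol in the table used here. Probe sets with several symbols named no gene. The 16941 gene symbols were set against a current gene table, in which 14546 were current, 2300 matched through 1 synonym and 95 did not match. Symbols are printed as in the platform table, with a current symbol where it differs. A gene's value on an array was the median of its probe sets, with a median of 13 probe sets per gene. Genes and probe sets whose mean over the 6 arrays lay at or above the 30th percentile were tested, which left 11859 genes and 201130 probe sets.

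Differences between knockdown and control were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the pair as a fixed block. Adjusted p-values are Benjamini-Hochberg values from this fit, with a threshold of 0.05, and tests are two-sided. With 3 pairs, an exact sign-flip test of a single gene cannot give a p below 0.25. The block came from the labels, which number the pairs. Over genes, the deviations of the arrays from their group means correlated at 0.17, 0.31 and 0.67 within pairs 1, 2 and 3, although control 1 correlated at 0.39 with knockdown 2 and control 2 at 0.39 with knockdown 1. No 2 arrays held identical values, and no slide or scan batch was given in the sources used here.

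Before the data were examined, 31 gene lists were fixed, covering the kinase family, proliferation, stress, inflammation, smooth muscle, matrix, signalling, metabolism and markers of other cell types. They were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. Unequal change between the probe sets of a gene was tested with limma's diffSplice F test in 13970 genes with at least 3 tested probe sets.

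Except where the text says otherwise, the genes named were chosen by a rule set before the data were examined. It took the 12 largest changes in each direction among genes past the threshold that moved the same way in all 3 pairs. Where fewer passed, it added those with the smallest unadjusted p among genes of that direction in all 3 pairs with an absolute log2 fold change of at least 0.5. Uncharacterised loci and sex-linked control genes were passed over. It also took up to 4 members of each list with the smallest unadjusted p, every member of the kinase family list, and the 5 genes with the smallest adjusted p for exon usage.

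The tests were tried on simulated data with the design of 3 pairs. Among 11859 simulated genes, the gene fit recovered 93.3% of genes changed 2-fold and 100% of those changed 4-fold, with 8.67 false calls per run on average. Each run held 100 genes changed by each fold, and many true changes loosen the Benjamini-Hochberg cutoff. These shares therefore do not carry over to data with few calls, where MMP12, at a log2 difference of -1.26, did not pass. Among 201130 simulated probe sets, the recovered shares were 1% at 2-fold and 79.7% at 4-fold, with 4.67 false calls. A list shifted by 0.4 was called in 100% of runs at the preset correlation and in 0% with an estimated correlation. The simulated genes varied independently, so these runs do not check the preset correlation for lists whose members move together. With 0% recovered, a list that does not pass with an estimated correlation is not shown to be unmoved. With 100 genes changed at 1 probe set, the exon usage F test recovered 100% of them with 35 false calls among 13984 genes. With nothing changed, the exon usage F test still called 5 genes per run on average among 13984, and its Simes form called 92.

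The alternatives were no block, the pair as a random block, centring of arrays on their medians, quantile normalization, eBayes with trend and robust settings, the mean or the median of only the brighter probe sets as the gene value, no filter, a filter at the 50th percentile, the other list and exon usage tests, each pair left out in turn, and both other offsets.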

Results

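Expression was measured on 6 exon-level arrays of human coronary artery smooth muscle cells, 3 with a vector control and 3 with shRNA against the L insert of CK1-alpha, in 3 pairs. CK1-alpha is a serine/threonine kinase, and its L-insert form, CK1-alpha-LS, is described in the series title as a nuclear kinase that responds to hydrogen peroxide. The comparison asks which transcripts differ when this form is knocked down. The first principal component held 56.1% of the variance between arrays and set pair 3 apart from pairs 1 and 2, and the second held 19.0% and set control 2 apart. In the limma fit, 365 of 11859 genes differed between pairs. The median gene differed between knockdown and control by -0.10, -0.088 and 0.050 in pairs 1, 2 and 3. List medians and counts above or below 0 are not centred on these values.

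Across CSNK1A1, the gene of CK1-alpha, no difference between knockdown and control was detected. Its gene value was 9.52 ± 0.30 in control and 9.60 ± 0.29 in knockdown (mean ± SD, log2, n = 3 each). The log2 difference was 0.080 (SE 0.15, limma adjusted p = 0.994), with -0.18, 0.32 and 0.10 in pairs 1, 2 and 3. By array, the level was 9.79, 9.57 and 9.21 in controls 1, 2 and 3 and 9.61, 9.89 and 9.30 in knockdowns 1, 2 and 3. Of its 23 probe sets, 18 had a fitted difference below 0, 3 were lower in all 3 pairs and 0 passed the threshold. The differences ran from -0.38 to 0.14, so the median-based gene value and most single probe sets differed in sign. In pairs 1 and 3 the gene value's differences were those of 1 probe set at the median level, 2880939. That probe set had the highest fitted difference of the 23, so the gene value stands little for the others. In pairs 1, 2 and 3, 21, 14 and 8 of the probe sets were lower in knockdown. Which probe set, if any, lies in the L insert was not determined here, and a probe set outside it also reads isoforms without the insert, so these values do not check the knockdown of CK1-alpha-LS. The sign of the gene value turned when the mean of the probe sets was used (-0.10) and without pair 2 (-0.041).

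**Figure D1:**
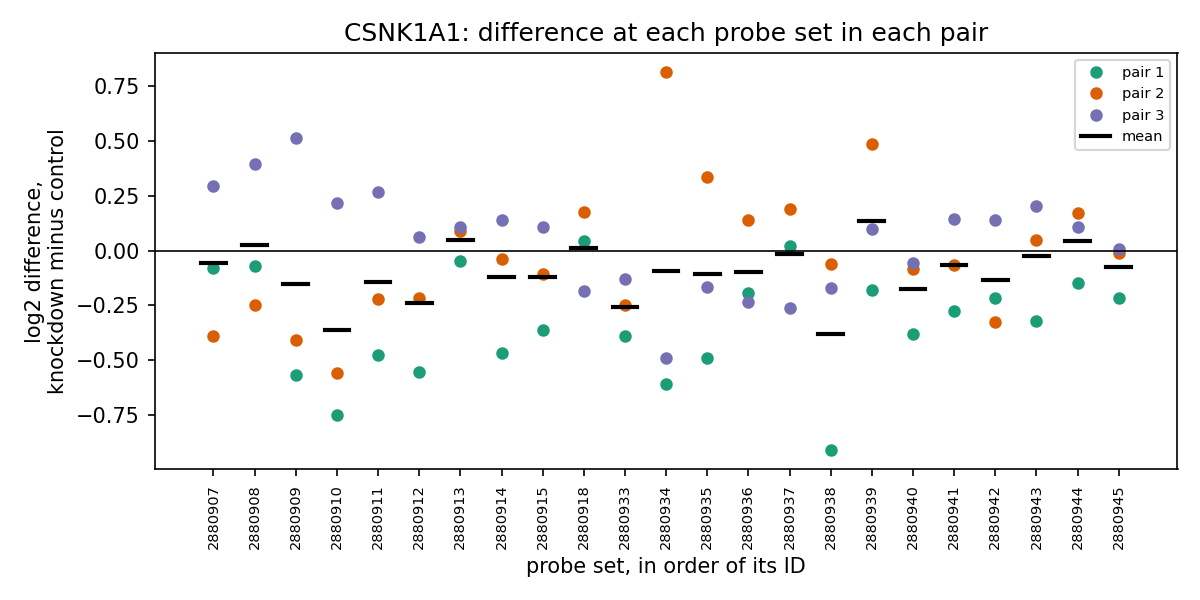
Log2 difference between knockdown and control (vertical axis) at each of the 23 probe sets of CSNK1A1 (horizontal axis, in order of probe set ID). Coloured points are the 3 pairs and black lines their mean; the means lie between -0.38 and 0.14, and 18 of them are below 0.

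The other casein kinase genes did not pass the threshold. CSNK1G3 had the largest difference, -0.37 (SE 0.15, limma adjusted p = 0.994), followed by CSNK1E at -0.28 and CSNK1A1L at 0.17. Without pair 2 CSNK1E and CSNK1A1L lay at -0.062 and 0.011. CSNK1D, CSNK1G1 and CSNK1G2 differed by -0.042, 0.049 and -0.027, values that moved by over 1.5 times or turned with 1 pair left out. CSNK1D lay at -0.074 without pair 2 and -0.0056 without pair 3. CSNK1G1 ranged from -0.093 without pair 3 to 0.22 without pair 2, and CSNK1G2 from -0.13 without pair 3 to 0.056 without pair 2. HNRNPC, an RNA-binding protein placed on the same list, differed by -0.12.

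Knockdown cells had less mRNA of the matrix-degrading enzyme stromelysin-1. MMP3 fell from 9.62 ± 1.59 in control to 7.81 ± 1.12 in knockdown (mean ± SD, log2, n = 3 each). It was 3.52-fold lower, a log2 difference of -1.82 (SE 0.20, 95% interval -2.27 to -1.37, limma adjusted p = 0.0495), with -1.53, -2.49 and -1.43 in pairs 1, 2 and 3. The SD of its 3 pair differences was 0.58. The SE and interval rest on a variance drawn toward that of other genes, so they are not the precision of these 3 pairs alone. MMP3 was the 1 gene of 11859 past the threshold. At an unadjusted p under 0.05 there were 526 genes, 183 higher and 343 lower, where 593 were expected by chance. Among single probe sets limma called 0 of 201130, with 8651 at an unadjusted p under 0.05 and 10056 expected, and with trend and robust settings it called 7. The MMP3 call sat at the threshold: its adjusted p was 0.9995 without the pair block, 0.107 without pair 1, 0.0711 without pair 3, and between 0.00165 and 0.9995 over all alternatives. Without pair 2 its adjusted p was 0.00165 and 3 genes were called in place of 1, with HIST1H1D and KCNE4 added, which are named after their values were seen.

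The rule added 11 genes lower in knockdown, chosen for being lower in 3 of 3 pairs, and none passed the threshold (limma adjusted p = 0.874 for each). They included the macrophage elastase MMP12, with a log2 difference of -1.26 (SE 0.22), the membrane peptidase MME (neprilysin) at -1.11 (SE 0.24), the cytokine IL24 at -0.98 (SE 0.21) and the thrombin inhibitor SERPIND1 (heparin cofactor) at -0.83 (SE 0.17). Smaller values were those of ANXA3, an annexin, at -0.75, the carboxypeptidase inhibitor LXN at -0.73, lactotransferrin, LTF, at -0.70 and the NKG2D ligand ULBP2 at -0.69. The adhesion molecule NRCAM, FAM89A and the membrane protein CDCP1 lay at -0.65, -0.65 and -0.64. Over the alternatives, the highest values of FAM89A, LTF and ULBP2 were -0.16, -0.22 and -0.23. In MMP12 and MME, pair 2 had the largest difference, -1.99 and -2.02, against -0.71 and -0.65 in pair 3, and without pair 2 MME lay at -0.66.

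In the other direction 0 genes passed. The 12 named by the same rule had limma adjusted p-values from 0.874 to 0.929 and were higher in 3 of 3 pairs, as the rule required. SOST, which encodes the Wnt inhibitor sclerostin, had a log2 difference of 0.89 (SE 0.22, and 0.53 without pair 2) and UACA one of 0.73 (SE 0.16). The chemokine CXCL12 lay at 0.69 (SE 0.16, and 0.17 at its lowest over the alternatives) and the secreted protein SCUBE3 at 0.67 (SE 0.17). AKR1C1, an aldo-keto reductase, lay at 0.75 (SE 0.18), but from 1 probe set of a gene with close paralogs. PRLH, PLXNA4, TMEM11, NPTX1, NCRNA00086, CEP170L (now CEP170P1, a pseudogene) and GPR56 (now ADGRG1) lay at 0.66, 0.65, 0.62, 0.61, 0.60, 0.58 and 0.55. Over the alternatives, the lowest values of TMEM11 and NPTX1 were -0.069 and 0.032.

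**Figure D2:**
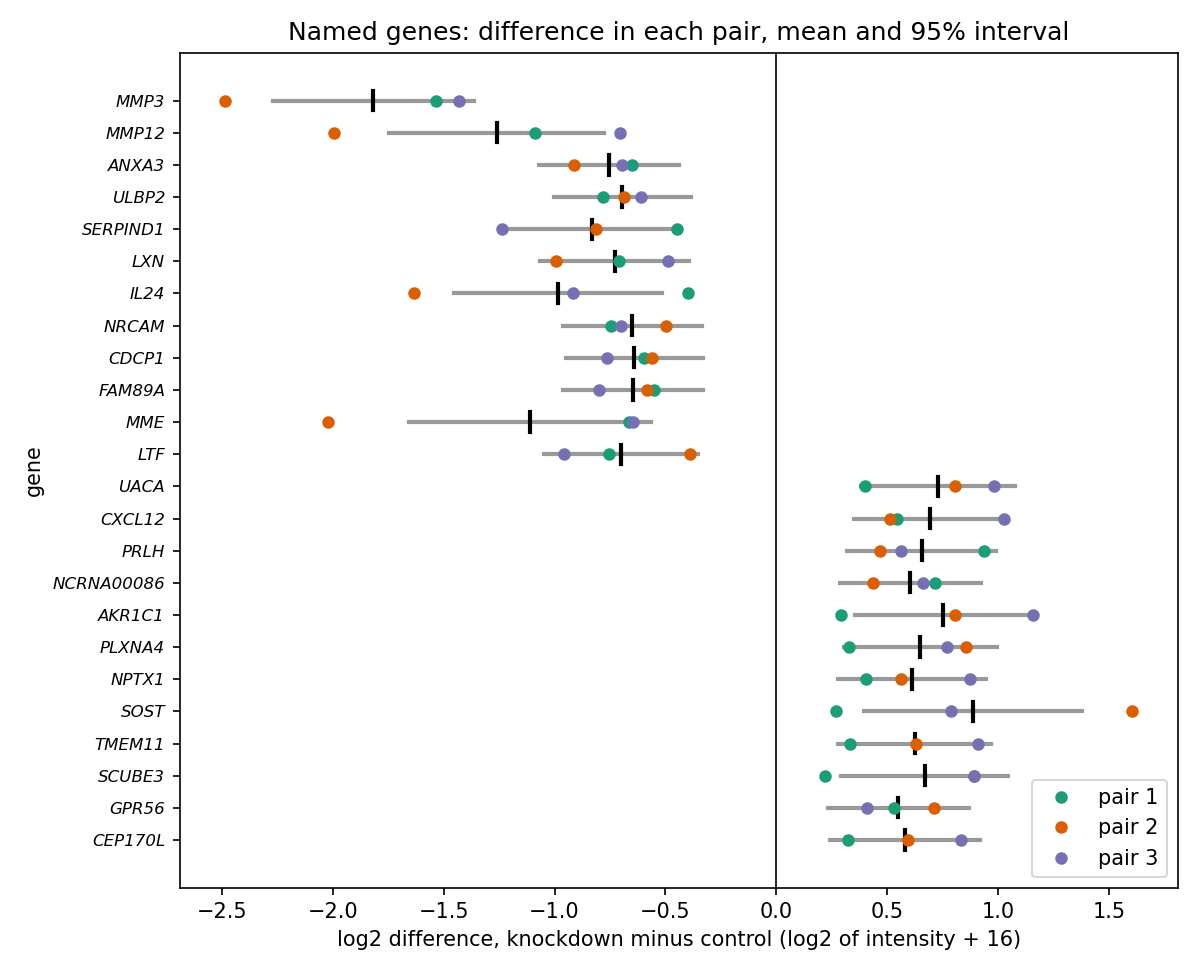
Log2 difference between knockdown and control (horizontal axis) for the 24 named genes. Coloured points are the 3 pairs, black ticks their mean and grey bars the 95% interval of the limma fit; MMP3 lies at -1.82, and it alone passed the threshold.

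Inflammatory and secreted genes mostly had lower values in knockdown, in lists called at a preset correlation and not by the other list tests. On the NF-kB and inflammatory activation list, 27 of 31 measured members had values below 0 and 10 were lower in all 3 pairs, with a median log2 difference of -0.27 (camera adjusted p = 6.9e-06). With an estimated correlation the call was lost (adjusted p = 0.578), as it was by fry (adjusted p = 0.326). The estimated correlation was -0.024 here and -0.027 in the secreted factor list, not above the preset 0.01. In the G2/M, G1/S, ribosomal protein and TGF-beta lists below it was 0.89, 0.68, 0.60 and 0.21, far above the preset value. The test with an estimated correlation recovered 0% of shifted lists in simulation, and fry was not tried there. A call lost by either test, for these lists or those below, does not show an unmoved list. After adjustment over all genes 0 of the 31 rose or fell. Adjusted over the list alone, 3 fell: the granulocyte growth factor CSF3, by 0.63, the cytokine IL1A, by 0.58, and the neutrophil chemokine CXCL5, by 0.68. IL32 lay at -0.59 without passing, and without pair 3 CXCL5 and IL32 lay at -0.39 and -0.34. The median of the list was -0.26, -0.37 and -0.071 in pairs 1, 2 and 3.

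The list of secreted factors of senescent cells, which shares 11 members with the NF-kB list, had a median of -0.32 over 19 members, 17 of them below 0 and 8 lower in all 3 pairs (camera adjusted p = 3.8e-05). This list too lost its call with an estimated correlation (adjusted p = 0.578) and by fry (adjusted p = 0.326). Over all genes 1 member fell, MMP3. Over the list alone 3 fell, MMP3, CSF3 and IL1A, and the chemokine CXCL3 lay at -0.46 without passing. Endothelial markers moved with both lists in pair 2, where their median was -1.09, but not in pairs 1 and 3, where it was 0.19 and 0.096. Against the median gene of each array, their mean level was 0.079 in control 2 and -0.66 in knockdown 2. On the other arrays it lay between -0.87 and -0.35. Control 2 also stood apart on the second principal component, so large differences in pair 2 cannot be told apart from a trait of that array.

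Matrix proteases and their inhibitors did not pass as a list of 22 members (camera adjusted p = 0.32), of which 7 were lower in all 3 pairs. Over all genes 1 fell, MMP3, and over the list alone 2 fell, MMP3 and MMP12. The cathepsins CTSS and CTSK lay at -0.68 and -0.84, and without pair 2 at -0.32 and -0.12. In CTSK the difference in pair 2 was -2.29.

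Genes of cell division had a positive average shift that the pairs did not share. The G2/M list, of genes such as CDC20, NUSAP1, PLK1 and CCNA2 (0.55, 0.41, 0.35 and 0.40), had a median of 0.26 over 32 members, with 29 above 0 (camera adjusted p = 3.7e-08, adjusted p = 0.813 with an estimated correlation). Its median was 0.92 in pair 1, -0.38 in pair 2 and 0.19 in pair 3, and 0 members were higher in all 3 pairs. Without pair 1 its shift against all other genes turned to -0.093 (adjusted p = 0.0926). G1/S and DNA replication genes, with UHRF1 at 0.29, MCM5 at 0.29, CDC45L (now CDC45) at 0.28 and the histone mRNA binding protein SLBP at -0.17, had a median of 0.090 over 31 members (camera adjusted p = 0.0137, adjusted p = 0.813 with an estimated correlation) and medians of 0.48, -0.42 and 0.11 in pairs 1, 2 and 3. Without pair 1 that list's shift was -0.14 (adjusted p = 0.0122), and the call was lost without the pair block (adjusted p = 0.0856), with the mean of the probe sets (0.0536) and with no filter (0.0518). Without pair 1 the members named with values above 0 in both lists lay between 0.011 and 0.11, and SLBP lay at -0.11.

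The remaining called lists were ribosomal proteins and TGF-beta targets. All 34 measured ribosomal protein genes had values below 0, with a median of -0.14 (camera adjusted p = 0.00055, adjusted p = 0.813 with an estimated correlation), and RPL31, RPL27, RPL22 and RPSA lay at -0.35, -0.50, -0.35 and -0.28, the last 3 at -0.12, -0.19 and -0.16 without pair 2. The list's median was 0.060 in pair 1, -0.35 in pair 2 and -0.16 in pair 3. Against the median gene of each array, its mean level rose from 3.25 in control 1 to 3.44 in knockdown 1. It fell from 3.58 to 3.31 in pair 2 and from 3.52 to 3.31 in pair 3, so pair 1 went the other way. TGF-beta targets had a median of 0.12 over 24 members, 14 of them above 0 (camera adjusted p = 0.0107, adjusted p = 0.813 with an estimated correlation), with the co-receptor ENG at 0.38, the transcriptional regulators ID1 and ID3 at 0.47 and 0.32, and TGFB2 at -0.31. Without pair 2 ID1 and ID3 lay at 0.27 and 0.20, and without pair 1 TGFB2 lay at -0.080. This list's median was -0.17 in pair 1, against its direction, and 0.029 and 0.21 in pairs 2 and 3. In both lists 0 members passed. Without pair 2 and without pair 3 the ribosomal list had adjusted p-values of 0.427 and 0.119 and the TGF-beta list 0.191 and 0.193.

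**Figure D3:**
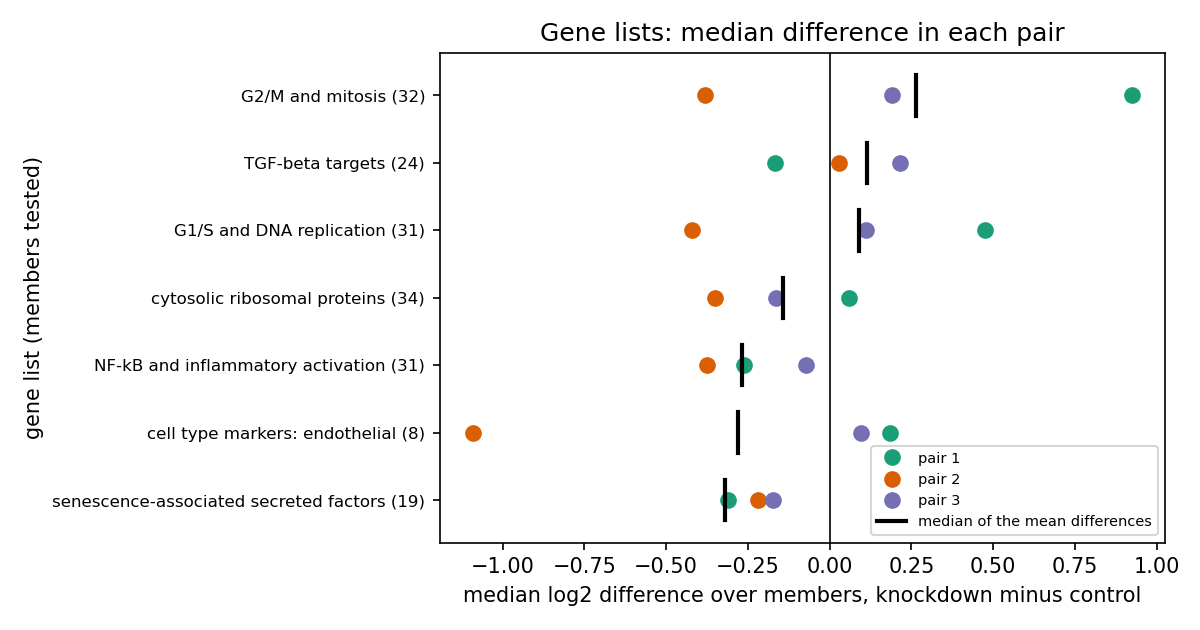
Median log2 difference over list members (horizontal axis) for the 6 lists past the camera threshold and, for comparison, the endothelial markers, which did not pass; member counts are in brackets. Coloured points are the 3 pairs and black lines the median of the mean differences; the NF-kB and secreted factor lists lie below 0 in each pair, and the G2/M list lies at 0.92, -0.38 and 0.19.

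Lists of smooth muscle identity and redox genes did not pass with the chosen settings, but 2 of them did under alternatives at the preset correlation. The synthetic list passed with the filter at the 50th percentile (adjusted p = 0.0028) and without pair 1 (0.0090), and not with an estimated correlation (adjusted p = 0.732 and 0.841). The matrix list passed with that filter (0.0432), without pair 1 (0.0356) and without pair 2 (0.0121), and not with an estimated correlation (adjusted p = 0.758, 0.841 and 0.877). The contractile genes had 12 members above and 12 below 0 (camera adjusted p = 0.828), among them gamma smooth muscle actin, ACTG2, at -0.51, the coactivator MYOCD at -0.54 and the calponins CNN1 and CNN2 at -0.36 and -0.34. Without pair 1 MYOCD and CNN1 lay at -0.30 and -0.22. Synthetic and osteochondrogenic genes (camera adjusted p = 0.104) included S100A4 at 0.57, KLF4 at 0.54, BMP2 at -0.36 and SOX9 at 0.34, with KLF4 at 0.34 without pair 3 and SOX9 at 0.20 without pair 2. On the matrix list (camera adjusted p = 0.104), elastin, ELN, lay at 0.76, tenascin-C, TNC, at -1.15, LAMA4 at -0.41 and POSTN at -0.46. The difference in TNC was -0.75, -2.54 and -0.17 in pairs 1, 2 and 3, and without pair 2 ELN, TNC and POSTN lay at 0.44, -0.46 and -0.21. NRF2 targets (camera adjusted p = 0.312) had AKR1C1 past the threshold over the list alone, with the cystine transporter SLC7A11 at 0.41, OSGIN1 at 0.31 (0.21 without pair 2) and FTL at -0.19. Antioxidant enzymes and NADPH oxidases (camera adjusted p = 0.352) had 10 of 21 members lower in all 3 pairs, and passed by fry after quantile normalization (adjusted p = 0.0234). The hydrogen peroxide-producing oxidase NOX4 lay at -0.87 with pair differences of 0.20, -2.68 and -0.11, SOD3 at 0.62 (0.17 without pair 3), GPX7 at -0.27 and GPX4 at -0.26.

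Signalling and growth lists did not pass with the chosen settings either, and 5 of them did under alternatives at the preset correlation. Growth factors and receptors (camera adjusted p = 0.942) included HBEGF at -0.73, PTGER4 at 0.42, HGF at 0.61 and FGF2 at -0.31. The difference in HGF was 0.072, 0.10 and 1.65 in pairs 1, 2 and 3, and without pair 3 it was 0.086 and that of PTGER4 0.19. Without pair 2 HBEGF lay at -0.48. Hedgehog genes (0.591) had GAS1 past the threshold over the list alone, at -0.50, with FOXF1 at -0.50, HHIP at 0.29 and GLI3 at -0.18. Under an alternative GAS1 lay at only -0.060. Without pair 2 HHIP and GLI3 lay at 0.18 and -0.037, and without pair 1 FOXF1 lay at -0.33. The adjusted p was 0.233 for Wnt targets, with TCF7 at 0.39, 0.917 for the circadian clock, with NR1D2 at -0.46, 0.312 for immediate early genes, with JUN at -0.29, 0.098 for interferon response genes, with IFIT3 at 0.63 (0.34 without pair 3), and 0.128 for p53 targets, with the stress cytokine GDF15 at -1.18 and CCNG1 at -0.39. It was 0.08 for replication-dependent histones, 0.774 for the casein kinase list and 0.497 for splicing factors. In GDF15 the pair differences were -0.69, -2.30 and -0.54, and without pair 2 it lay at -0.61. The interferon list passed without pair 2 (adjusted p = 1.4e-13) and without pair 3 (0.0459), and not with an estimated correlation (adjusted p = 0.877 and 0.904). Its median was 0.62, -0.47 and 0.10 in pairs 1, 2 and 3. The Wnt list passed with the mean of the probe sets (0.0402) and with the brighter probe sets (0.0076), and not with an estimated correlation (adjusted p = 0.786 and 0.738). The histone list, with 3 to 5 members tested, passed with the brighter probe sets (0.0017), with the filter at the 50th percentile (0.00083), without pair 2 (1.3e-06) and without pair 3 (0.0459). With an estimated correlation none of these calls held (adjusted p = 0.738, 0.758, 0.877 and 0.904). Without pair 2 the p53 and splicing lists passed as well (0.0295 and 0.0098), and not with an estimated correlation (adjusted p = 0.877 for both).

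Metabolic and protein folding lists gave camera adjusted p-values of 0.281 for oxidative phosphorylation (COX7B at -0.40), 0.182 for hypoxia and glycolysis (PDK1 at -0.40), 0.668 for cholesterol synthesis (SCD at -0.46), 0.12 for the unfolded protein response (VLDLR at -0.40) and 0.355 for heat shock proteins (CRYAB at 0.75). SCD and CRYAB lay at -0.26 and 0.28 without pair 2. At the preset correlation, oxidative phosphorylation passed without pair 1 (0.0361), hypoxia and glycolysis with the brighter probe sets (0.0201), and the unfolded protein response with those (0.0291), without pair 1 (0.0208) and without pair 3 (0.0388). With an estimated correlation they did not (adjusted p = 0.841, 0.738, 0.851, 0.841 and 0.904). Marker lists of other cell types did not pass with the chosen settings, with 0.337 for endothelial, 0.319 for leukocyte, 0.46 for fibroblast and 0.46 for epithelial genes. In pair 2 the endothelial markers PECAM1, CDH5 and TIE1 differed by -1.80, -1.21 and -1.18. The leukocyte list had CD14, at -0.54 (-0.31 without pair 1), past the threshold over the list alone, but CD14 turned to 0.22 under an alternative. At the preset correlation, the endothelial list passed without pair 1 (0.0041), the epithelial list without pair 3 (0.0077) and the leukocyte list with the brighter probe sets (0.0410). With an estimated correlation they did not (adjusted p = 0.841, 0.904 and 0.738).

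Exon usage differed in 1 of 13970 genes. In MYL6B, a myosin light chain gene, probe set 3417440 was higher in knockdown by 1.06 and probe set 3417443 lower, at -0.99, each in 3 of 3 pairs (diffSplice F test, adjusted p = 0.0217). The next genes did not pass (adjusted p = 0.289 each): ACYP2, where probe set 2482366 lay at -1.84, RGS3, MID2 and the stromelysin MMP10. CSNK1A1 had an adjusted p of 1. At an unadjusted p under 0.05 there were 504 genes, and the simulation with nothing changed called 5 genes on average. The Simes form called 75 genes, and the MYL6B call ended without a filter and with the filter at the 50th percentile, where 0 genes passed. It was also lost with each pair left out in turn, when 4, 1 and 2 other genes were called without pairs 1, 2 and 3.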

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

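The offsets of 1 and 64, and the other list tests within each alternative, were chosen after the data had been seen, and the other alternatives before. The gene count of 1 went to 0 with no replicate block, with the pair as a random block, with centred arrays, after quantile normalization, with trend and robust settings, with the mean of the probe sets, without a filter and with both other offsets. It stayed 1 with the brighter probe sets and with the filter at the 50th percentile. With 1 pair left out it ranged from 0 to 3, the highest without pair 2, and rested on fewer arrays. The MMP3 difference itself kept its direction in all 14 alternatives, from -2.01 to -1.48. The probe set count of 0 became 7 with trend and robust settings and stayed 0 in the other alternatives. The difference in CSNK1A1 turned to -0.10 with the mean of the probe sets and ranged from -0.041 to 0.21 with 1 pair left out. The count of 6 lists went to 0 with an estimated correlation and 0 by fry, and rose to 11 with the brighter probe sets. It was 5 with no replicate block, 5 without a filter, 9 with the filter at the 50th percentile, and 8 to 10 with 1 pair left out. With the mean of the probe sets it was 6, with the Wnt list in place of the G1/S list. Over the alternatives 13 more lists were called 23 times at the preset correlation, 0 of these with an estimated correlation (adjusted p = 0.732 to 0.904) and 0 by fry (0.783 to 0.971) in the same alternative. With 1 pair left out the shift of the G1/S list ranged from -0.14 to 0.34 and that of the G2/M list from -0.093 to 0.59, both lists turning without pair 1. The NF-kB and secreted factor lists kept direction in all 14 alternatives and their calls in 12, all but the estimated correlation and fry, although centring, the other list tests and leaving out the block cannot move their shift against all genes. The exon usage count of 1 became 75 with the Simes form, 0 without a filter, 0 with the filter at the 50th percentile, 2 with an offset of 1, 0 with an offset of 64, and 1 to 4 with 1 pair left out. Among named genes, 26 values changed sign under an alternative, none of them past the threshold, and 1902 kept direction and side. With 1 pair left out, 81 of 143 named genes turned or shrank by over 1.5 times, 28, 45 and 16 of them without pairs 1, 2 and 3. Leaving out the block ended the calls of MMP3 and of the G1/S list and changed no other call of a named gene or called list. The cause of these changes was not tested. Dim genes may be limited by signal over background, which was not measured. About 18.1% to 20.1% of probe sets lay below an intensity of 16.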

Other observations

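The counts over other splits of the arrays were planned before their results were seen, and the other tests here were chosen after the results they bear on had been seen. Grouping genes by the letters of their symbols gave 195 families of at least 8 tested genes, of which camera called 5 at the preset correlation and 0 with an estimated correlation. The CC chemokines (CCL, 9 genes) had a mean log2 difference of -0.41, with -0.43, -0.67 and -0.12 in pairs 1, 2 and 3 (adjusted p = 0.0217, 0.999 with an estimated correlation). Keratin-associated proteins (KRTAP, 40 genes) had a mean of 0.10 (adjusted p = 0.00014, 0.999 with an estimated correlation) and histones (HIST, 23 genes) one of 0.20, with 0.43, -0.018 and 0.20 in pairs 1, 2 and 3 (adjusted p = 0.0017, 0.999 with an estimated correlation). Against the mean of all genes each of these 3 families kept its sign after quantile normalization and with offsets of 1 and 64. The other called families, PRSS at 0.20 and RPL at -0.10 against that mean, kept theirs too, so this does not set the 3 apart.

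MMP10, a stromelysin like MMP3, lay below the filter as a gene. Among its 8 tested probe sets, 3388797 and 3388802 differed by -1.68 and -1.74 and were lower in 3 of 3 pairs, while 3388805 differed by 0.18. MMP11, also named a stromelysin, was tested and lay at 0.30, with 0.23, 0.43 and 0.23 in pairs 1, 2 and 3, without passing. The collagenase MMP1, also secreted, lay at -0.10. These genes were picked after their values were seen.

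Across all genes, the pair differences agreed little: Pearson's r across genes, which are not independent replicates, was -0.023 for pairs 1 and 2, -0.12 for pairs 1 and 3 and 0.15 for pairs 2 and 3. Of 11849 genes, 867 (7.32%) were higher and 1903 (16.1%) lower in all 3 pairs, where chance gives 12.5% each. With each pair centred on its median, 1372 (11.6%) were higher and 1410 (11.9%) lower.

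The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold, 5 of the 10 splits gave at least the real count of 1, and the highest other gave 21. For probe sets, 10 of 10 gave at least the real 0, and the highest other gave 3. For gene lists, 5 of 10 gave at least the real 6, and the highest other gave 13. For exon usage, 10 of 10 gave at least the real 1, and the highest other gave 58. Of the 10 splits, 6 part only 1 pair, and with the pair block they come down to 3 fits, each of 1 pair's own difference between knockdown and control. These 6, which hold the highest counts of genes, probe sets, lists and exon usage, are no comparison without change. Among the 4 splits that part all 3 pairs, the other 3 gave 0 genes each, 2, 12 and 10 lists, and 9, 1 and 10 genes of exon usage.

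The NF-kB and secreted factor genes were lower in all 3 pairs by their list medians, and the smallest shift of the NF-kB list with 1 pair left out was -0.18, so no single pair decided it. Of 10000 random lists matched on mean level, 0% had a median below that of the NF-kB list over the mean of the pairs, 0.01% in pair 1 and 0% in pair 2, and 0.01% and 0.06% below that of the secreted list in pairs 1 and 3, which argues against a lowering of bright genes as a class there. In pair 3 the NF-kB list's median of -0.071 lay within the middle 95% of random lists (-0.081 to 0.11, with 3.56% below). The genes matched to it on level had a median of 0.016 there (95% bootstrap interval 0.0056 to 0.027). They were not below 0, but they lay below the median of all tested genes in pair 3, which was 0.050. A lowering of bright genes as a class thus stays open for the NF-kB list in pair 3. For the secreted list in pair 2 the random lists do not decide, since its median of -0.22 lay within their range (2.58% below). The genes matched to it had a median of -0.075 there (-0.089 to -0.063). The median of all tested genes in pair 2 was -0.088, so the matched genes did not lie below the median gene. Fewer endothelial cells in the knockdown cultures would lower their markers in every pair. The mean of these markers was 0.24 in pair 1, -0.88 in pair 2 and -0.011 in pair 3, so pair 1 went against this. It could not be told apart further, since they averaged 0.12 over pairs 1 and 3, within 2 standard errors of 0 (SE 0.067 over 8 members). That error is over genes, which are not replicates of the cultures. An off-target effect of the shRNA was not tested, so an effect of the knockdown may remain only as a hypothesis.

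The mitotic genes moved apart between pairs, with a median of 0.92 in pair 1 and -0.38 in pair 2. Scaling of dim genes as a class is argued against by the matched random lists, of which 100% lay below the list's median in pair 1 and 0% in pair 2. The growth state of single cultures may differ, and was not tested here, so the list's positive shift stays open.

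MMP3 was lower in all 3 pairs, and 15 of its 16 probe sets were lower in each pair, which argues against a few faulty probe sets. Array medians lay between 6.63 and 6.84 in log2, too close for overall scaling to account for the size of its difference. Quantile normalization could thus change it little, and left it at -1.82, although its limma adjusted p was then 0.166. Cross-hybridisation with MMP10 could not be tested without probe sequences. A response of MMP3 to the knockdown may be a hypothesis to follow, and its call rests on the pair block.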
